A study of Mus musculus with 5 samples.

How the data were processed

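Reads from 5 libraries of mouse embryonic stem cells were analysed, 1 library per group. In MeDIP-seq, sonicated and denatured DNA was pulled down with 2 µg of an antibody to 5-methylcytosine (5mC), and in hMeDIP-seq with 2 µg of an antibody to 5-hydroxymethylcytosine (5hmC), per the labels' protocols. In MethylCap-seq, 1 µg of fragmented DNA was captured with 2 µg of a GST fusion of a methyl-CpG binding domain (MBD), and the bound DNA was eluted at 600 mM or at 800 mM NaCl. Per the labels, the enriched libraries came from gene-trap clones of the E14 line, while the input was chromatin DNA of TNG-A cells, an E14 derivative that carries a GFP reporter at the Nanog locus. The input is thus from another line than the libraries it was compared with.

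The deposited files list 1 aligned read of 35 bp per line, with its position in mm9 and its strand. Reads were aligned with BWA 0.5.8 to mm9, per the submitters' processing notes. The deposited column 5 is a read count and was 1 in every line. The meaning of the deposited column 4, which holds 0 or 1, is not given in the sources used here; it was 1 for 7.88% of reads in the 600 mM eluate, 8.22% in the 800 mM eluate and 8.38% in the input, and 0 for every read of MeDIP and hMeDIP. No position and strand carried more than 1 read in MeDIP, hMeDIP and input, or more than 2 in the MethylCap libraries, so the files hold reads from which duplicates had been reduced. This caps the height of dense signals and in particular the share of mitochondrial DNA.

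Reads were assigned by their midpoint to 1 kb bins of chromosomes 1 to 19 and X, and scaled to RPM, with the reads on these chromosomes as the total. The ratio of a bin to input was (RPM + 0.5)/(input RPM + 0.5), and a bin counted as enriched at a ratio of 3 or more. Of 2638957 bins, 2440090 held a read in at least 1 library, with a median of 7 input reads. The pseudocount pulls ratios of bins with few reads toward 1. Printed folds of single bins thus lie below the raw ratio where they exceed 1, and above it where they are under 1. Unless a bootstrap is named, intervals are exact 95% intervals of raw read ratios (Clopper-Pearson on the conditional binomial). They cover counting error only, since reads without molecular identifiers are not independent molecules. Where a library had no read in a bin, the fold was computed against 3 reads, which leaves out the counting error of the other library, and the lower end of the exact interval is given beside it. With 1 library per group no test between conditions was possible, no p-value is given, and no difference has a replicate check.

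The bin size, threshold, pseudocount, overlap and chromosome comparisons were fixed before the data were examined. Without gene models of mm9 no gene was named. The rule set for that case names the 10 bins with the highest ratio to input per library, among bins with at least 5 input reads, and a minimum of 20 reads in the library was carried over from the rule for genes. The 10 bins with the largest difference between the antibodies and the 5 between the eluates, in each direction, were likewise carried over from the rule for genes after the data were examined. Named bins are extremes of the values they are ranked by. Also chosen after the data were examined were the counts of bins that differ between the 5hmC and 5mC antibodies, the classes of bins by MethylCap reads, the 1 Mb windows (at least 3000 input reads), the groups of 5hmC bins, and the 8-fold and 16-fold thresholds for the eluates, which were computed along with 3-fold and 4-fold ones.

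All 4 enriched libraries were compared with the same input, whose chance values they share. For overlaps and correlations the input reads were therefore also split at random so that each library had its own part, and parts of the input were compared with each other as libraries without enrichment. Such parts differ by counting error only, so they do not show the background of a library from another line or preparation. The number of bins that counting error alone would put past a threshold between 2 libraries was simulated by redistributing each bin's reads in proportion to depth.

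The calling rule was tested on simulated libraries of the real depths, with 200 bins per fold size among 2638957. Input rates were smoothed over 10 kb, and enriched bins were placed only where at least 5 input reads were expected. All other bins stayed at the input level, whereas the median ratios of the real libraries were 0.704 to 0.839. It called 97.5 to 100.0% of bins with a true 10-fold enrichment, 58.5 to 70.5% at 6-fold and 11.5 to 17.0% at 4-fold, and between 3 and 107 unchanged bins per library. The rule was thus strict under these settings, and the number of enriched bins understates moderate enrichment. The rates may differ in the real libraries, with their lower background and bins of fewer input reads. Of 2000 simulated intervals, 97.0% held the true ratio.

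CpG islands, classes of CpG density, promoters, gene bodies and the gene lists were planned and not analysed here, because they need the sequence or gene models of mm9, which were not used here. Alternatives tried were 1 read per position and strand, read positions moved 100 bp from the 5′ end, a pseudocount of 0.1 RPM, a 5-fold threshold, a minimum of 3 input reads and 500 bp bins. Further alternatives chosen after the data were examined were no reads with a 1 in column 4, equal depth (7507520 reads), scaling to the median ratio, autosomes only, split input, chromosome shares scaled to the median ratio, 4-fold and 8-fold thresholds between the antibodies, and groups of 5hmC bins called with 1 part of the input and measured over the other. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.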

Results

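The distribution of 5mC and 5hmC was profiled in mouse embryonic stem cells grown without feeders in serum and leukaemia inhibitory factor. The 4 enriched libraries were a MethylCap eluate at 600 mM NaCl (10495409 reads), a MethylCap eluate at 800 mM NaCl (7539403 reads), MeDIP with the 5mC antibody (10487251 reads) and hMeDIP with the 5hmC antibody (18563204 reads), and the input held 18722723 reads. There was 1 library of each, so differences below are between libraries, with intervals for counting error only. Positions are in mm9.

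To ask where each mark was concentrated, 1 kb bins at 3-fold or more over input were counted. The 5hmC antibody enriched 47119 bins, which held 12.8% of its reads, and the 5mC antibody enriched 60886 bins with 16.8% of its reads. The 600 mM eluate had 81281 enriched bins with 23.2% of its reads and the 800 mM eluate 104250 bins with 31.2%. Input compared with itself, which shows counting error only, gave 361 bins with a pair of parts of 9339823 and 9336442 reads, and 3025 and 3054 bins with smaller parts of 6223158 and 6226907 reads over one of 6226200. Of the runs of enriched bins, 79.3 to 88.4% per library were a single bin long, under a rule that misses most neighbours of moderate enrichment, so run lengths do not measure the width of the signal. Runs of 5 or more bins numbered 508 and 768 in the 600 mM and 800 mM eluates, 115 in MeDIP and 60 in hMeDIP.

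The longest run in both antibody libraries lay near the distal end of chromosome X, at 166419001–166439000 in MeDIP. Reads over it were 20.2-fold over input with the 5mC antibody, 12.1-fold with the 5hmC antibody, 31.2-fold in the 600 mM eluate and 22.9-fold in the 800 mM eluate. Input was also dense over this run, with 369 reads in 20 bins, where the median covered bin held 7. The input is from another line, and the copy number of the region in the lines was not measured. A run on chromosome 15 at 76004001–76014000 was also high in all 4, at 15.6-fold in hMeDIP, 12.1-fold in MeDIP and 60.6-fold in the 600 mM eluate. By contrast, a run on chromosome 4 at 129879001–129887000 was 23.6-fold over input in hMeDIP and 18.7-fold in MeDIP, but 2.62-fold and 1.58-fold in the 600 mM and 800 mM eluates. A run on chromosome 17 at 3006001–3025000 was 15.1-fold over input in the 600 mM eluate, 1.07-fold in MeDIP and 0.480-fold in hMeDIP.

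At the scale of 1 Mb, the 4 libraries were high and low in the same places. The window on chromosome 8 at 123000001–124000000 was highest in both eluates and in MeDIP, at 5.08-fold, 5.06-fold and 3.86-fold over input, and was 3.51-fold in hMeDIP. The highest hMeDIP window was on chromosome 4 at 139000001–140000000, at 3.52-fold. A window on chromosome 4 at 112000001–113000000 was lowest in both antibody libraries, at 0.121-fold in MeDIP and 0.158-fold in hMeDIP. Across windows, which are not independent replicates, the log2 ratios of hMeDIP and MeDIP with separate parts of the input correlated with r = 0.540 at 1 kb, 0.786 at 10 kb, 0.916 at 100 kb and 0.967 at 1000 kb. Of the 2512 windows at 1000 kb, 2367 were autosomal, and X, low in all 4 libraries, may raise r. Separate parts of the input do not remove differences that the enriched libraries share against an input of another line. The covariance at 1 kb was 0.293 with separate parts of the input and 0.403 with the same part. Smaller parts of the input without enrichment, compared with 1 shared part, had a covariance of 0.164.

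To ask how far the signals of the 5hmC and 5mC libraries coincided, enriched bins were overlapped. Of the 5hmC bins, 21134 (44.9%) were also enriched with the 5mC antibody, 16221 (34.4%) in the 600 mM eluate and 16499 (35.02%) in the 800 mM eluate. Independent sets of the same sizes would share 1176, 1570 and 2013 bins. The shared counts were thus 18.0, 10.3 and 8.20 times the independent ones, and 12.9, 7.65 and 6.38 times with separate parts of the input. Parts of the input without any enrichment shared 160 bins where independent sets would share 3.79, so some of the excess may come from the shared input. At a 5-fold threshold the shares of the 7265 5hmC bins were 51.8% with the 5mC antibody, 22.8% in the 600 mM eluate and 18.2% in the 800 mM eluate.

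A total of 8056 bins (17.1% of the 5hmC bins) were enriched in all 4 libraries, and 17545 (37.2%) were enriched with the 5hmC antibody alone. Over the latter, summed reads were 3.35-fold over input in MeDIP and 2.34-fold in the 600 mM eluate, but bins chosen by a ratio to input tend to be low in that input. When such bins were called with 1 part of the input, the folds over the part not used for calling were 2.40 and 1.68. In 4346 5hmC bins (9.22%) both MethylCap eluates were below input, as they were in 60.2% of all bins with a read. These bins were chosen by their hMeDIP and MethylCap ratios, and MeDIP, which was not part of the choice, was at 4.49-fold over them and at 0.464-fold over all 1469982 bins below input in both eluates. Of these 4346 bins, 197 were below input with the 5mC antibody as well. The group was chosen as high in hMeDIP over the same input, which can make a low MeDIP ratio rarer. This count was not repeated with separate parts of the input. When the group was called with 1 part of the input (4120 bins), MeDIP was 3.86-fold over the other part.

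Among the named bins, those with the highest 5hmC ratio showed the same contrast between the antibodies and the MBD capture, and those with the highest 5mC antibody ratio did not. None of the libraries was a mock pulldown, so binding by both antibodies that does not depend on the marks was not tested. Of the 10 bins with the highest 5hmC ratio, all 10 were enriched with the 5mC antibody (6.09-fold to 29.3-fold), whereas 7 were under 2-fold in each MethylCap eluate. The first, on chromosome 5 at 36614001–36615000, held 292 hMeDIP reads against 6 input reads (19.8-fold, interval of the raw ratio 22.3 to 134.8), 47 MeDIP reads (6.09-fold), and 2 and 1 reads in the 600 mM and 800 mM eluates. A bin on chromosome 4 at 154062001–154063000 held 249 hMeDIP and 81 MeDIP reads and no read of either eluate. Of the 10 bins with the highest 5mC antibody ratio, all were also enriched in the other 3 libraries. Among them was a bin on chromosome 11 at 116607001–116608000, at 29.1-fold in MeDIP and 19.7-fold in hMeDIP.

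**Figure D1:**
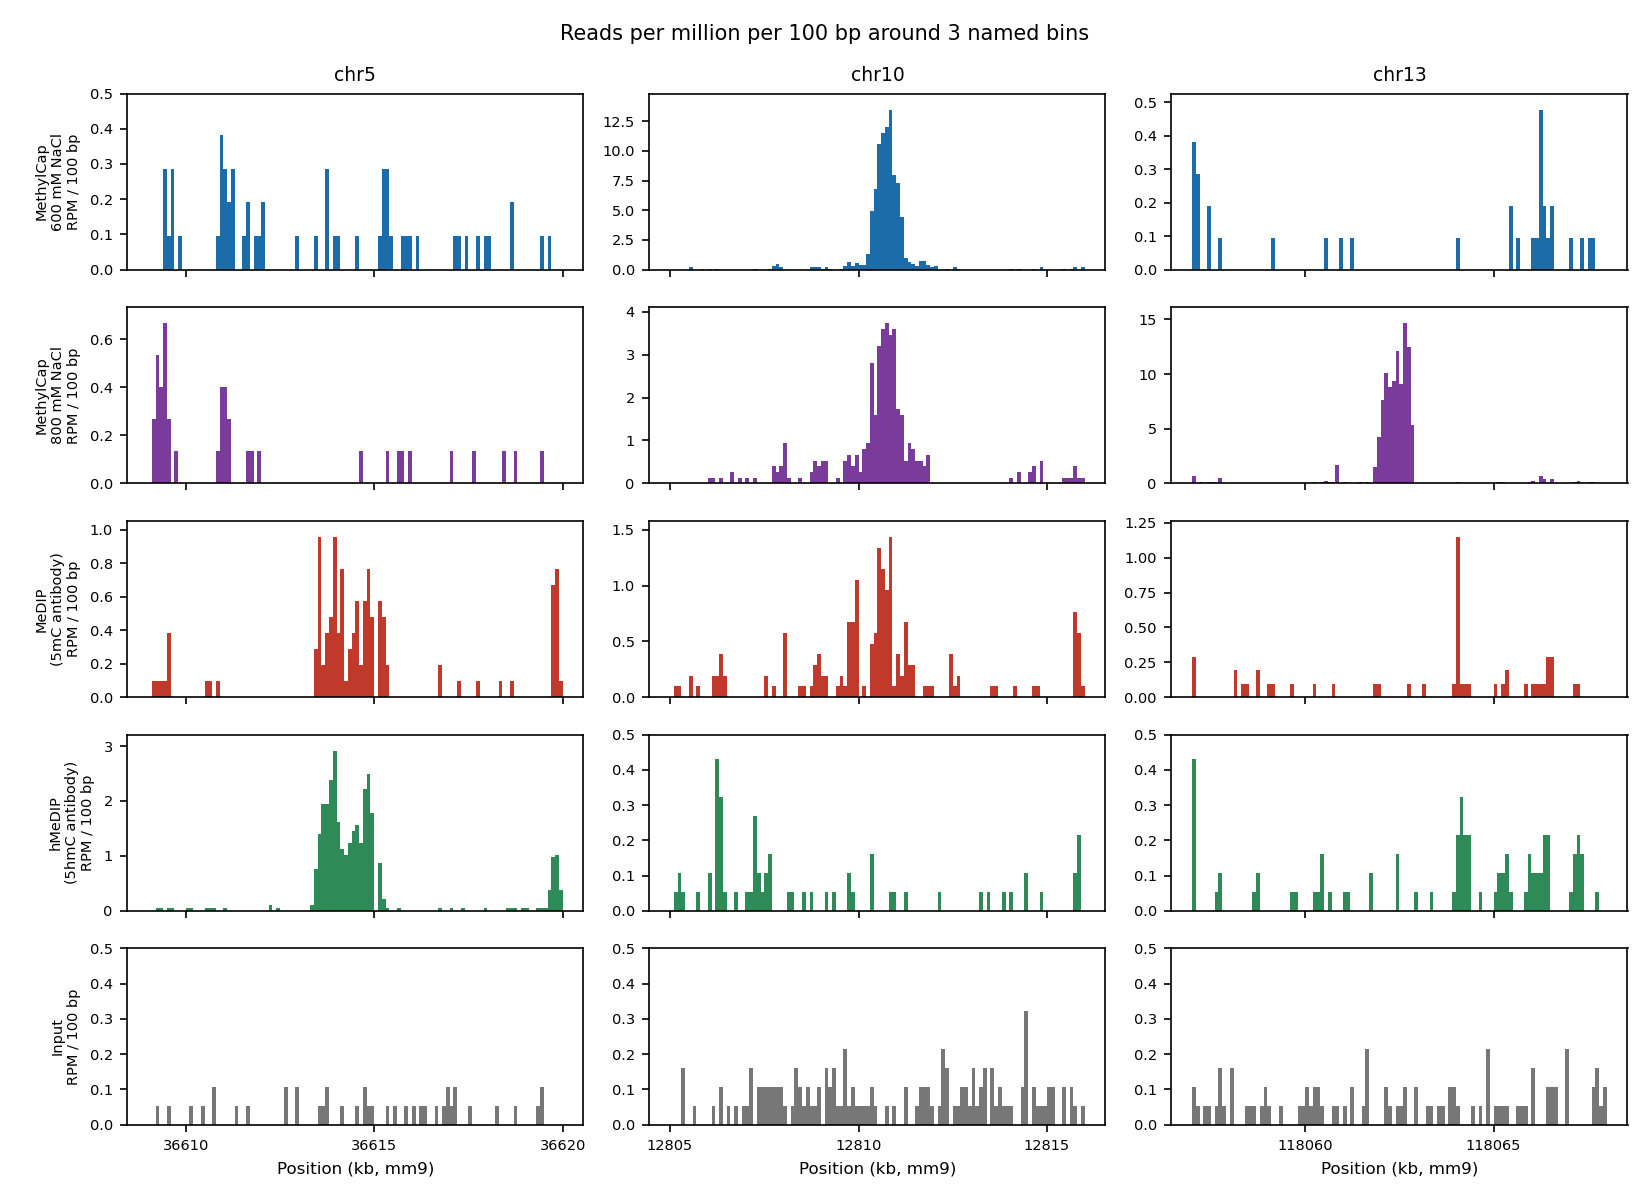
RPM in 100 bp steps (vertical axes, scaled per panel) against position in kb (mm9) for the 5 libraries around 3 named bins, on chromosomes 5, 10 and 13 from left to right. The left region was high with the antibodies and held 2 and 1 MethylCap reads in its central bin, the middle one was highest in the 600 mM eluate with 5 hMeDIP reads, and the right one held 672 reads at 800 mM and 0 at 600 mM.

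Bins with high 5mC signal and hMeDIP near the level of a typical bin were also found. The bin with the highest 600 mM ratio, on chromosome 10 at 12810001–12811000, held 726 reads in the 600 mM eluate (75.3-fold over input), 180 in the 800 mM eluate (26.4-fold) and 64 in MeDIP (7.14-fold), but 5 in hMeDIP against 8 in input (0.829-fold, interval of the raw ratio 0.162 to 2.19). A bin on chromosome 15 at 72640001–72641000 was 57.5-fold over input at 600 mM, 11.0-fold in MeDIP and 0.818-fold in hMeDIP, and a bin on chromosome 7 at 134754001–134755000 was 30.0-fold, 10.1-fold and 0.722-fold. Of the 10 bins with the largest excess of the 5mC over the 5hmC antibody, all were enriched in the 600 mM eluate (3.14-fold to 75.3-fold) and 8 were below input with the 5hmC antibody. The interval of the raw hMeDIP ratio included the input level in each of these 8. The median hMeDIP ratio over bins with at least 3 input reads was 0.839, so a depletion of 5hmC below background was not shown. The 10 bins with the largest excess in the other direction were all below input in MeDIP and at 2.46-fold to 4.07-fold in hMeDIP. The first, on chromosome 16 at 59529001–59530000, held 78 hMeDIP reads and no MeDIP read, which is at least 14.7-fold higher with the 5hmC antibody if the absent reads are set to 3, and 11.6-fold at the lower end of the exact interval.

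Compared directly, 11748 bins were at least 3-fold higher with the 5hmC antibody and 9916 at least 3-fold higher with the 5mC antibody, where counting error alone would give 45 and 13. After a random thinning to equal depth the counts were 20359 and 19269, where counting error alone would give 980 and 955. Which antibody had more such bins depended on the setting, and the majority turned to the 5mC antibody with 500 bp bins (8513 and 10471) and at higher thresholds (1606 and 1725 at 4-fold, 215 and 384 at 5-fold, 2 and 22 at 8-fold). At 1 Mb, 5hmC was highest relative to 5mC on chromosome 15 at 103000001–104000000 (1.62-fold, interval 1.53 to 1.72) and next to it at 102000001–103000000 (1.47-fold), followed by chromosome 11 at 97000001–98000000 (1.45-fold). It was lowest on chromosome 9 at 3000001–4000000 (0.6002-fold, interval 0.580 to 0.621). The log2 ratio of the antibodies had an SD of 0.175 across autosomal windows.

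The ratio of hMeDIP to MeDIP reads shifted with the density of MethylCap signal. hMeDIP also had the smaller share of its reads in enriched bins, 12.8% against 16.8% in MeDIP. A library with more background would give such a shift without a change of the marks, and the possibilities were not separated. In bins without a 600 mM read, hMeDIP was 1.26-fold of MeDIP (1.21 to 1.31 across autosomes), and this fell step by step to 0.752-fold (0.708 to 0.799) in bins with 21 to 40 reads and 0.647-fold (0.480 to 0.810) in bins with 81 or more. Over the same classes, the ratio to input of hMeDIP rose from 0.450-fold to 4.47-fold at 41 to 80 reads and was 3.19-fold at 81 or more, and that of MeDIP rose from 0.358-fold to 6.36-fold and was 4.92-fold at 81 or more.

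**Figure D2:**
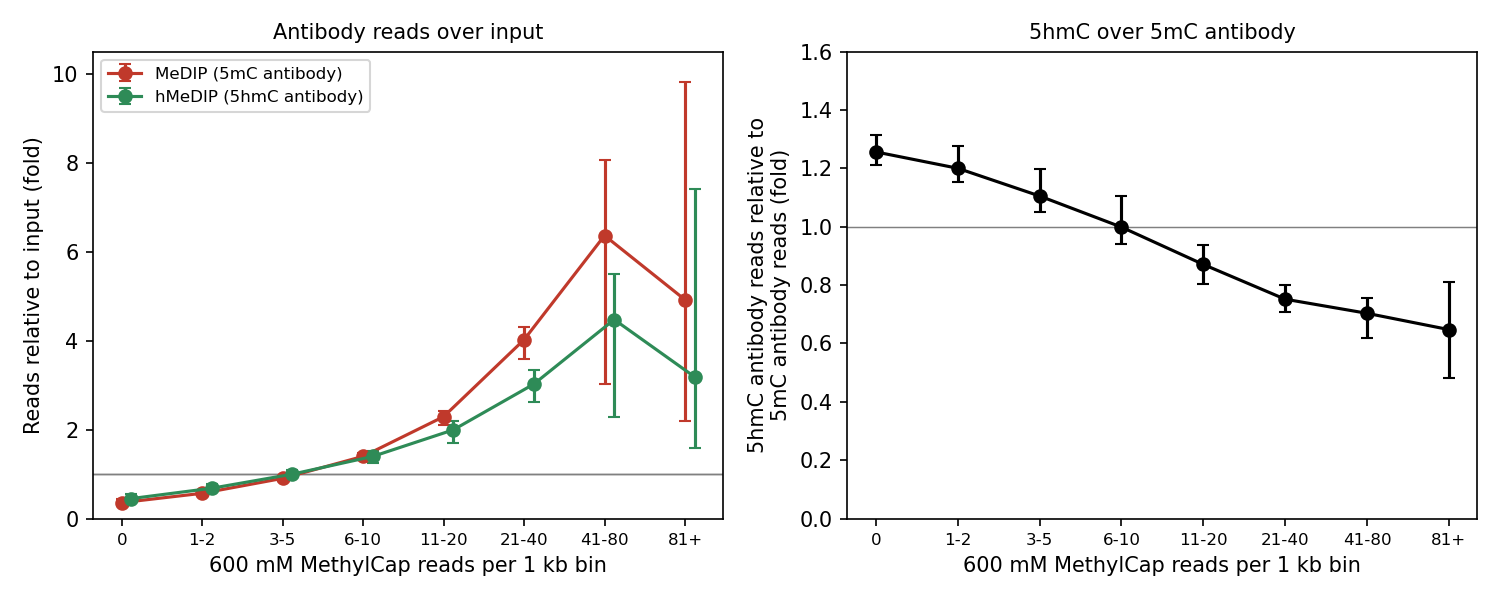
Left, summed reads relative to input (fold) of MeDIP and hMeDIP in 1 kb bins with at least 3 input reads, classed by their number of 600 mM MethylCap reads; right, hMeDIP relative to MeDIP in the same classes. Points are values over all bins of a class and bars span the lowest to the highest autosome; hMeDIP relative to MeDIP falls from 1.26 to 0.647.

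The salt steps were compared to ask what the higher salt released. Most of the signal was shared: 56625 bins were enriched in both eluates, 69.7% of the 600 mM bins and 54.3% of the 800 mM bins. Compared directly, 5393 bins were at least 3-fold higher at 800 mM and 2720 at least 3-fold higher at 600 mM, where counting error alone would give 227 and 401. With a pseudocount of 0.1 RPM the majority turned, with 96388 and 150211 bins, but counting error alone then gives 83927 and 75327. At 8-fold, 1016 bins were higher at 800 mM and 0 at 600 mM, and at 16-fold 287 and 0.

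The bins with the largest excess at 800 mM held many reads, whereas the median over the 1016 bins at 8-fold was 71 reads at 800 mM. On chromosome 11 at 75578001–75579000 there were 1078 reads at 800 mM (126.1-fold over input) and 9 at 600 mM (1.19-fold). On chromosome 13 at 118062001–118063000 there were 672 reads at 800 mM and none at 600 mM, at least 312.2-fold higher at 800 mM if the absent reads are set to 3 (253.2-fold at the lower end of the exact interval), with 1 MeDIP, 4 hMeDIP and 9 input reads. Of the 10 bins with the highest 800 mM ratio, 7 were under 2-fold in MeDIP and 1 was enriched there. The bins with the largest excess at 600 mM were small by comparison. Among them, a bin on chromosome 11 at 22872001–22873000 held 382 reads at 600 mM and 49 at 800 mM, with MeDIP at 6.56-fold and hMeDIP at 0.839-fold. The others held 22 to 31 reads at 600 mM and 0 or 1 at 800 mM. Of the 5 bins, 2 were enriched in MeDIP and 3 were under 2-fold there.

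**Figure D3:**
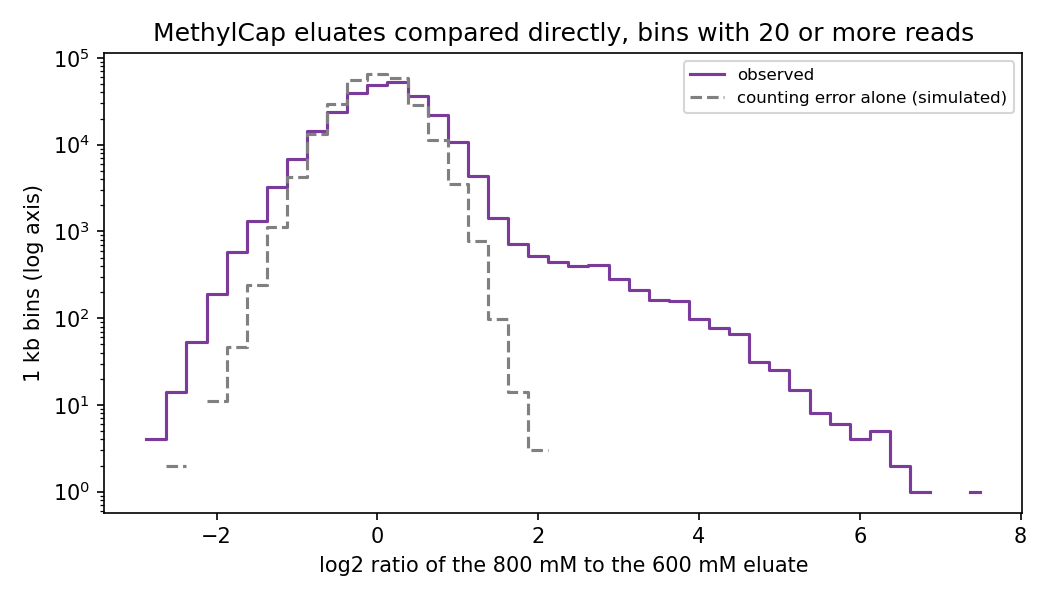
Number of 1 kb bins (log axis) by log2 ratio of the 800 mM to the 600 mM eluate, for bins with at least 20 reads in the 2 eluates together; the dashed line is a simulation with counting error alone. The observed distribution has a long tail toward the 800 mM eluate, with 1016 bins at 8-fold or more.

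Read shares of whole chromosomes were compared with input. Chromosomes 5, 8, 11, 17 and 19 were high in all 4 libraries, for example chromosome 5 at 1.28-fold in each eluate, 1.20-fold in MeDIP and 1.18-fold in hMeDIP, and chromosomes 3 and 14 were low. Chromosome X stood apart from every autosome, at 0.275-fold (0.274 to 0.277) in the 600 mM eluate, 0.271-fold (0.269 to 0.273) in the 800 mM eluate, 0.389-fold (0.387 to 0.391) in MeDIP and 0.440-fold (0.439 to 0.442) in hMeDIP. Between 236 and 475 enriched bins per library lay on X, which was 0.388 to 0.567% of a library's enriched bins. X held 142638 of the 2440090 bins with a read. The input came from another line, and copy numbers of the autosomes, X and Y in the lines were not measured independently. The shares of autosomes and X may thus hold differences in copy number. Within the input, the median per 10 kb was 86 reads on X from 5 to 15 Mb and 53 from 15 to 166 Mb, against 74 on autosomes, with the boundaries chosen after the values were seen. Mitochondrial DNA was at 0.0519-fold in the 600 mM eluate (531 reads), 0.871-fold in the 800 mM eluate (6390 reads), 0.315-fold in MeDIP and 0.459-fold in hMeDIP. The 800 mM value was 1.24-fold when the median ratio to input was set to 1.

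**Figure D4:**
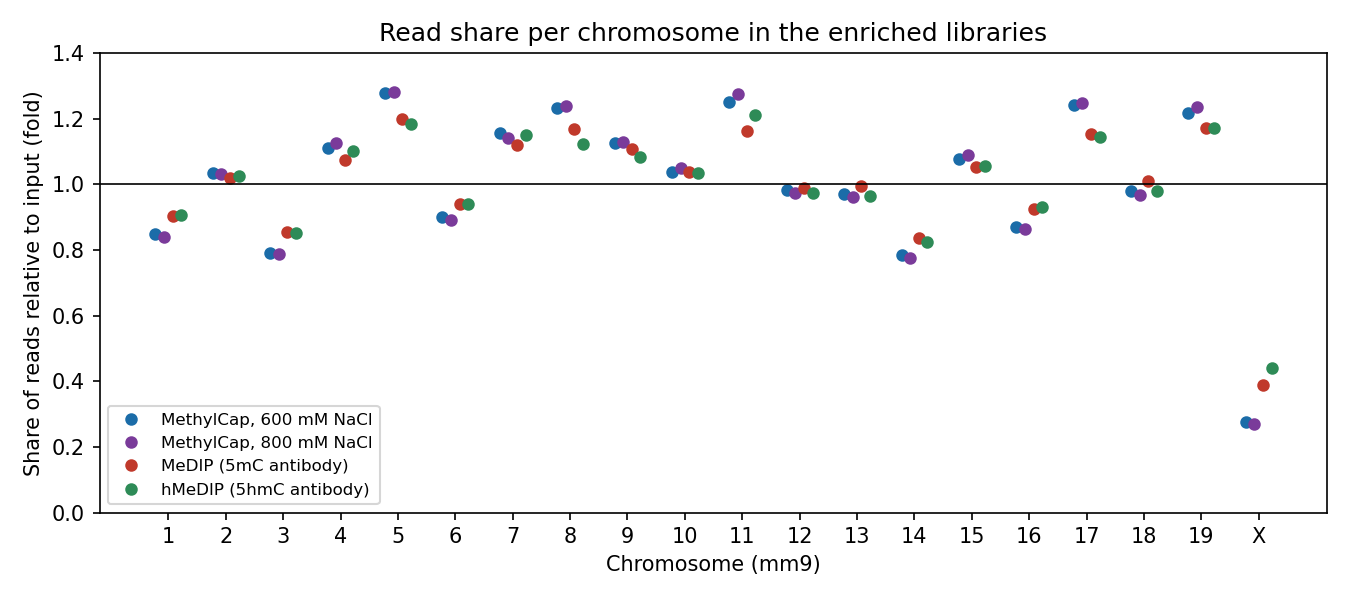
Share of reads relative to input (fold) for chromosomes 1 to 19 and X in the 4 enriched libraries, 1 point per library; counting intervals are narrower than the points. Chromosome X lies at 0.271 to 0.440, below every autosome.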

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

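All tests in this part were chosen after the results were seen. Chromosome Y and unplaced sequence were outside the bins analysed, and some of them carried more signal than the input. Chromosome Y was 35.5-fold over input in the 600 mM eluate, 36.6-fold in the 800 mM eluate, 44.4-fold in MeDIP and 39.7-fold in hMeDIP, with 90 input reads against 1789, 1325, 2232 and 3543. The input, from another line, held almost no reads of Y, so these folds and those of Y-linked unplaced sequence do not show enrichment of Y by the antibodies or the capture. Without reads with a 1 in column 4 the folds were 134.9, 137.2, 166.3 and 148.8, so their size depends on these reads. Y-linked unplaced sequence was 132.3-fold, 128.6-fold, 186.4-fold and 148.6-fold over its 66 input reads. Unplaced sequence of unknown chromosome was 1.86-fold over input in the 600 mM eluate, 2.42-fold in the 800 mM eluate and 2.86-fold in MeDIP, but 0.837-fold in hMeDIP. Unplaced sequence of autosomes and X was 1.29-fold and 1.05-fold in the 600 mM and 800 mM eluates, but 0.928-fold in MeDIP and 0.719-fold in hMeDIP.

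The low share of chromosome X in all 4 enriched libraries may have a technical part, since the input is from another line. If 1 copy number of X, shared by the enriched libraries and different from the input, were the whole cause, X would differ between these libraries no more than autosomes do. The log2 difference between hMeDIP and the 800 mM eluate was 0.710 for X and -0.140 to 0.136 for the autosomes, which argues against it. This pair of libraries was taken because X differed most in it, and the autosomes were compared in the same pair only. The enriched libraries are labelled as from clones, and a copy number that differs between clones, or a difference between single libraries, was not tested. Less modification of X as the whole cause stays open, because its test depended on the window size. In 10 kb windows without a MethylCap read (235 on X, 411 on autosomes) the 5mC antibody ratio to input was higher on X by 0.305 log2 units. The interval from a bootstrap over windows was 0.125 to 0.494, and it treats windows as independent, which neighbours may not be. In 1 kb bins without such a read the difference was -0.656, in the opposite direction. Choosing bins for having no MethylCap read selects differently on X and autosomes, so neither value decides, and a mixture of copy number and modification remains open.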

How the results depend on the processing

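Settings other than those named before the data were examined (no reads with a 1 in column 4, equal depth, scaling to the median, autosomes, split input, 4-fold and 8-fold thresholds, groups of 5hmC bins called with part of the input) were chosen after the data were seen. In the settings run for them, no ratio by which the bins were named changed direction. Mitochondrial DNA at 800 mM did, from 0.871 to 1.24 with the median ratio set to 1. The antibody with more bins in the direct comparison turned with 500 bp bins (8513 with 5hmC higher, 10471 with 5mC higher) and at 4-fold (1606, 1725), 5-fold and 8-fold (2, 22), and the eluate with more bins turned with a pseudocount of 0.1 RPM. Of the 70 ratios of named bins, 63 rose by more than 1.5 times with a pseudocount of 0.1 RPM (1.05 to 4.98 times, median 1.93), so their size depends on it. Under the other settings 4 of 320 values moved by more than 1.5 times (0.521 to 1.69 times), the largest on chromosome 7 at 89920001–89921000, which fell to 24.8-fold over input in the 600 mM eluate without column 4 reads. Bin counts stayed within 1.5 times under 1 read per position, moved read positions, 500 bp bins, at least 3 input reads, no column 4 reads and autosomes only, and the counts of enriched bins, shared bins and bins that differ between the eluates also at equal depth; shared bins also with split input. With a pseudocount of 0.1 RPM, which lets bins with few reads pass, enriched bins were 235658, 250881, 205373 and 181395 (600 mM, 800 mM, MeDIP, hMeDIP), 5hmC bins shared 81414, 80777 and 96184 with the first 3, the eluates differed in 96388 (800 mM higher) and 150211 bins, and the antibodies in 179818 (5hmC higher) and 122263, where counting error alone would give 77797 and 34527. At 5-fold the same counts were 14470, 21349, 11380 and 7265, then 1657, 1320 and 3765, then 2157 and 27, then 215 and 384. In another random thinning to equal depth the antibodies differed in 20349 (5hmC higher) and 19067 bins. Setting the median ratio to 1 shifts all log2 ratios by the medians of -0.402, -0.507, -0.262 and -0.254 and gave 168710, 220253, 102199 and 83660 enriched bins and 36398, 39985 and 38164 shared ones. Chromosome X was then 0.364, 0.386, 0.467 and 0.525, mitochondrial DNA 0.0686, 1.24, 0.377 and 0.547, and chromosome Y 46.9 and 52.0 in the eluates. Shares of chromosome X without column 4 reads were 0.277 (600 mM), 0.380 (MeDIP) and 0.430 (hMeDIP), and with autosomes as the total 0.266, 0.262, 0.378 and 0.429. Mitochondrial DNA at 800 mM was 0.792 with 1 read per position, 0.683 without column 4 reads and 0.842 with autosomes as the total, and 0.445 in hMeDIP without column 4 reads. Chromosome Y without column 4 reads was 134.9, 137.2, 166.3 and 148.8. Apart from the constructions named, the cause was not tested. Not run were a mapping quality filter, scaling by CpG-poor bins, all alternatives for CpG islands, CpG classes, promoters, gene bodies and gene lists, and moved read positions for chromosome shares, which do not use them. No paired analysis was possible because each group has 1 library.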

Other observations

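All tests in this part were chosen after the results were seen. The 1016 bins at least 8-fold higher at 800 mM than at 600 mM formed 894 separate runs, at most 5 bins long, on all 20 chromosomes analysed, and held 1.25% of the 800 mM reads. Their median was 71 reads at 800 mM, 2 at 600 mM, 10 in input, 3 in MeDIP and 7 in hMeDIP. Bins next to them were 2.86-fold over input at 800 mM and 1.18-fold at 600 mM.

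Reads marked in column 4 or duplicates as the cause would remove these bins, but 91.9% stayed at 8-fold with unmarked reads, 1 per position and strand. DNA carried over without capture, if like the input, would follow the input. Input reads alone, thinned to the depth of the 800 mM eluate, put 0 of the 1016 bins (and 2 bins in all) at 8-fold over the 600 mM eluate. With a median of 10 input reads, these bins could hardly reach 8-fold in that way. The outcome thus speaks only to carried-over DNA like the input, and DNA of another make-up was not tested. Methylated DNA that only the higher salt releases would raise the 5mC antibody signal toward that of the 3666 other bins with at least 41 reads at 800 mM, which were 4.49-fold over input (2.40 to 6.81 across autosomes). The 1016 bins were at 0.649-fold (0.539 to 0.935). Their 5mC antibody reads were 0.979 times those of other bins with the same 600 mM and input reads (0.791 to 1.30 across autosomes), so the signal was that of background and the 5mC antibody gives no sign of such DNA. A candidate explanation left open is CpG-dense DNA held by the MBD protein without methylation; CpG density was known for 0 of the bins, because no mm9 sequence was used here. No replicate shows whether the bins recur.

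Column 4 was 0 for every MeDIP and hMeDIP read and 1 for some reads of the other libraries. The share of such reads per 1 Mb window of autosomes ranged from 5.10 to 26.5% of input reads and correlated between input and the 600 mM eluate (Spearman 0.922 across 2367 windows, which are not independent). It may mark reads with a mismatch that were removed from the antibody files. Removal predicts a slope of 1 for the log2 ratio of antibody to 600 mM reads on the log2 share of unmarked reads. The slope was 1.05 (chromosome bootstrap 0.550 to 1.74) for MeDIP and 1.14 (0.352 to 2.07) for hMeDIP, but 0.331 (0.224 to 0.439) and 0.294 (0.107 to 0.533) when the 600 mM ratio to input was added as a covariate. Both models were run and they disagree, so removal stays open.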
